A study of Mus musculus with 2 samples.

How the data were processed

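Uteri of mice given doxorubicin at 3 mg/kg, alone (DOX) or with anti-Müllerian hormone at 0.75 mg/kg (DOX plus AMH), were compared 4 h after treatment. The series text gives 2 weekly doses and mice of postnatal day 25, but for bulk sequencing, and the labels do not say whether these animals had the same schedule. Per the labels, uteri of 5 animals were pooled per group, dissociated with papain and collagenase A, and made into 1 library each with 10x Genomics 3' v3.1 chemistry. The authors processed the reads with Cell Ranger 7.0.0 on the mm10 build, and the deposited matrices hold raw UMI counts per gene and barcode. Their barcodes had been filtered before deposit, since the lowest total was 500 UMIs in both. The libraries held 129530270 and 97887259 UMIs over 9258 and 8083 barcodes for DOX and DOX plus AMH, with medians of 12674 and 9397 UMIs per barcode.

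Barcodes with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial UMIs passed, 7783 in DOX and 7065 in DOX plus AMH. Scrublet, run per library in scanpy 1.11.5 at its own threshold, called 447 and 320 of these doublets (5.74% and 4.53%), which were removed. The 7336 and 6745 cells left were clustered together without integration, on 2000 variable genes, 30 principal components and 15 neighbours, by the Leiden method at resolution 1 (igraph 0.11.9). Clusters were named from marker genes for stromal, smooth muscle, epithelial, vascular and lymphatic endothelial, pericyte, mesothelial, macrophage, dendritic, lymphocyte and other cells, and are called like those cells. A cluster stayed unnamed where its top genes held more markers of another class, or where it held no marker of its own while being shallow or of a rare class. The markers were fixed beforehand, and the way they were scored was set after the data had been seen. Markers of cells outside the uterine classes were summed over all kept cells. Classes with fewer than 50 cells in a library were left out of the comparisons.

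UMIs were summed per library and class and scaled to CPM over all genes. Each gene's log2 ratio, DOX plus AMH over DOX, has an exact 95% interval from the binomial split of its UMIs, and shares of cells have exact binomial intervals. With 1 library per group there are no replicates, so no test was made and genes were picked by size alone. A gene at 0 in 1 library was set against a floor of 3 counts. Genes at least 2-fold apart were counted among those with at least 100 UMIs and 20 CPM in the higher library. The 20 fixed lists covered p53 targets, DNA repair, apoptosis, AMH and BMP signalling, immediate-early genes, heat shock, NF-kB and chemokines, type I interferon, glucocorticoid, oestrogen and progesterone, NRF2 and the integrated stress response, and also extracellular matrix, Wnt, S phase, G2/M, histones, angiogenesis, epithelial differentiation and smooth muscle contraction. A list's result is the median log2 ratio of members with at least 20 UMIs, with an interval from 1000 Poisson draws, and its members were counted at 1.3-fold. The interferon gene Mx1 was missing from the annotation. Shares of cells with a UMI of Mki67 or Top2a were taken after thinning each cell to 2000 UMIs.

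Named genes followed a rule written before the data were examined, as were the comparisons, lists, markers, filters and most alternatives. It takes the 12 highest and 12 lowest ratios in stromal-like cells and 5 of each in epithelial-like, smooth muscle-like, vascular endothelial-like, mesothelial-like and macrophage-like cells, among genes at 0.2 or more of the CPM of their highest class, which guards against free RNA. That guard covers the 10 compared classes and unnamed clusters of at least 50 cells in a library, so free RNA of other cells can pass. The rule adds up to 4 members per list and class and 12 genes taken in every class, and leaves out mitochondrial, ribosomal protein and haemoglobin genes. Of the 632 pairs of gene and class it allows, the text uses a shorter set. The set was shortened by rank alone, to the first 2 members per list in stromal-like and smooth muscle-like cells and the first in other classes, after all had been run under every alternative. Genes of the other tissues and the genes that define clusters stand outside the rule and were looked at after their values were seen.

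The ratios and intervals were run on simulated Poisson counts with the depths of the stromal-like and mesothelial-like classes. There 95.5% of 14539 and 95.6% of 7430 intervals held the true ratio. Poisson counts are what the interval assumes, and they hold no spread between cells or pools. The simulation therefore checks the calculation only, not how well the intervals cover in these data. Of 100 genes simulated 2-fold lower, the interval excluded no difference for 98% in stromal-like and 97% in mesothelial-like cells. Alternatives were no cell filter, a stricter filter (2000 UMIs, 1000 genes, 10% mitochondrial), doublets kept, Leiden resolution 0.5, each library clustered on its own, TMM scaling, CPM over nuclear genes without ribosomal protein and haemoglobin genes, each cell weighted alike, cells thinned to 2000 UMIs, other minimum counts (10 and 50, or 100 and 200), a 1.5-fold bound, and no thinning or 4000 UMIs per cell. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9, and TMM factors came from edgeR 4.0.16 in R 4.3.3.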

Results

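Droplet libraries of mouse uterine cells were made from 2 groups of animals. One group, DOX, received doxorubicin at 3 mg/kg, an anthracycline that damages DNA through topoisomerase II. The other, DOX plus AMH, received the same dose with anti-Müllerian hormone at 0.75 mg/kg, a hormone of the TGF-beta family that signals through the receptor Amhr2. Uteri were taken 4 h after treatment and those of 5 animals were pooled per group, so each group is 1 library and no difference could be tested. The series text gives 2 weekly doses and mice of postnatal day 25 for bulk sequencing, and it is not stated whether the animals used here had the same schedule. The DOX library held 9258 barcodes and 129530270 UMIs, and the DOX plus AMH library 8083 barcodes and 97887259 UMIs. After filtering, 7336 and 6745 cells remained, with median depths of 13705 and 10109 UMIs, against the 10000 cells collected per group. Paired values are given for DOX first and DOX plus AMH second. A log2 ratio is DOX plus AMH over DOX, followed by its 95% interval, and every interval covers counting error only, not the spread between pools. Intervals of log2 ratios also leave out the spread between cells. The question was how uterine cells exposed to doxorubicin differed when the hormone was given with it. No library of untreated animals was analysed here, so no value is set against an untreated level.

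Stromal-like cells made up the largest class in both libraries and smooth muscle-like cells the next. Stromal-like cells were 66.4% (65.3 to 67.5) and 54.3% (53.1 to 55.5) of the kept cells, a lower share in DOX plus AMH. Smooth muscle-like cells were 12.3% (11.5 to 13.0) and 16.7% (15.8 to 17.6), a higher share. These differences of -12.2 and 4.43 percentage points kept their sign but moved with the cells counted. They were -8.03 and 5.71 without the keratin-led cluster 24, described below, and -8.61 and 2.84 with no cell filter. Pericyte-like cells were 3.12% and 5.50%, vascular endothelial-like cells 2.73% and 3.60% and mesothelial-like cells 1.19% and 2.05%. Macrophage or monocyte-like cells were 3.76% and 3.20%, dendritic-like cells 1.79% and 1.11%, lymphatic endothelial-like cells 1.62% and 0.830% and lymphocyte-like cells (T, NK or innate lymphoid) 1.05% and 1.22%. Epithelial-like cells were 3.68% and 1.82%, and this order turned around under 3 other settings. Median depths differed between the libraries, at 14813 and 10188 UMIs in stromal-like and 10250 and 9058 in smooth muscle-like cells.

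Clusters without a name held 1.24% and 8.38% of the kept cells. Cluster 24, led by the squamous keratin genes Krt14, Krt5, Krt15 and Krt13 with Ly6d and Spink5, held 7 and 486 cells, or 0.0954% and 7.21%, and so is almost wholly of the DOX plus AMH library. It lay nearest to the epithelial markers and stayed unnamed because its top genes held 0 epithelial markers and 1 mesothelial marker. That marker was the keratin gene Krt14 itself, so no mesothelial character is read from it. Cluster 27, led by 9030622O22Rik, BC048679 and Gkn3, held 0.954% and 0.356%, cluster 1, led by Gm15261 and Gm42620, 0.191% and 0.311%, and cluster 29, led by Gm10800 and Mmp12, 0% and 0.504%. Cluster 7 (Prc1, Hist1h1b, Cenpf, Top2a), cluster 11 (Mannr, Ptprb, Epas1) and cluster 23 (D5Ertd615e, Rbp7, Cldn5) were almost wholly of the DOX library, with 239 and 27, 70 and 0 and 41 and 1 cells, and such a cluster can stand for its library rather than for a cell type. Classes with fewer than 50 cells in a library were not compared, namely ciliated-like (67 and 28 cells), erythroid-like (3 and 33), glial-like (10 and 17) and neutrophil-like (2 and 12). The ciliated name is not borne out for the DOX cells, where its leading genes were hardly counted.

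**Figure D1:**
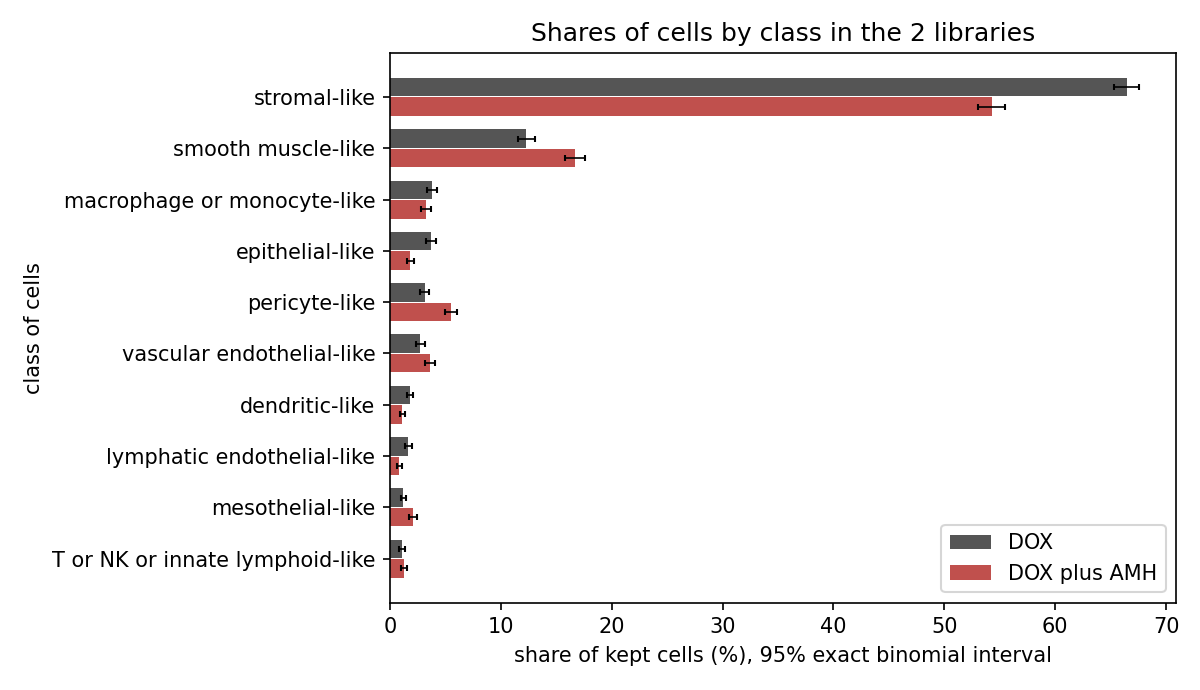
Share of kept cells in each class (percent, horizontal axis) for the DOX and DOX plus AMH libraries, with exact 95% binomial intervals as error bars. Stromal-like cells were 66.4% and 54.3%, smooth muscle-like cells 12.3% and 16.7% and pericyte-like cells 3.12% and 5.50%.

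Transcripts of the type I interferon response were lower in DOX plus AMH in most classes and those of the glucocorticoid response higher. The interferon list had a median log2 ratio below 0 in 10 of the 10 classes, from -3.21 in dendritic-like to -0.21 in mesothelial-like cells. By the summed CPM of the list, epithelial-like cells differed least, with 2229 and 2091. By its median the list differed least in mesothelial-like cells, where 5 of 19 genes were at least 1.3-fold lower. There the median of all counted genes was -0.17 and that of the list -0.06 under TMM scaling. Next by median were vascular endothelial-like cells, where 7 of 19 were lower. The vascular count includes cluster 11, which is of the DOX library alone, and in cluster 20 alone 16 of 19 were lower, with a median of -0.67 (-0.84 to -0.55). The glucocorticoid list lay above 0 in 10 of the 10 classes, from 0.56 in vascular endothelial-like to 0.97 in lymphatic endothelial-like cells. The p53 target list lay below 0 in 8 of the 10, with its lowest median, -1.06, in smooth muscle-like cells and its highest, 0.05, in lymphocyte-like cells. Its interval lay below 0 in 6 of the 10, spanned 0 in dendritic-like cells at -0.02 (-0.29 to 0.10) and lymphatic endothelial-like cells at -0.06 (-0.17 to 0.09), and in mesothelial-like cells the median, -0.17, was that of all counted genes. Clusters found almost wholly in DOX shift these medians too, since without them the p53 median was -0.27 (-0.36 to -0.12) in lymphatic endothelial-like cluster 17, and in vascular endothelial-like cells it was -0.28 (-0.48 to -0.06) in cluster 20 against -0.54 (-0.63 to -0.34) for the class. Immediate-early genes, which tissue dissociation also induces, had medians above 0 in 10 of the 10 classes, from 0.12 in dendritic-like to 0.85 in mesothelial-like cells. The p53 count was 9 under TMM scaling and 7 with CPM over nuclear genes alone. Under TMM scaling the immediate-early count was 8, with -0.02 in stromal-like and -0.01 in dendritic-like cells, while the interferon and glucocorticoid counts were 10 of 10 under each scaling.

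**Figure D2:**
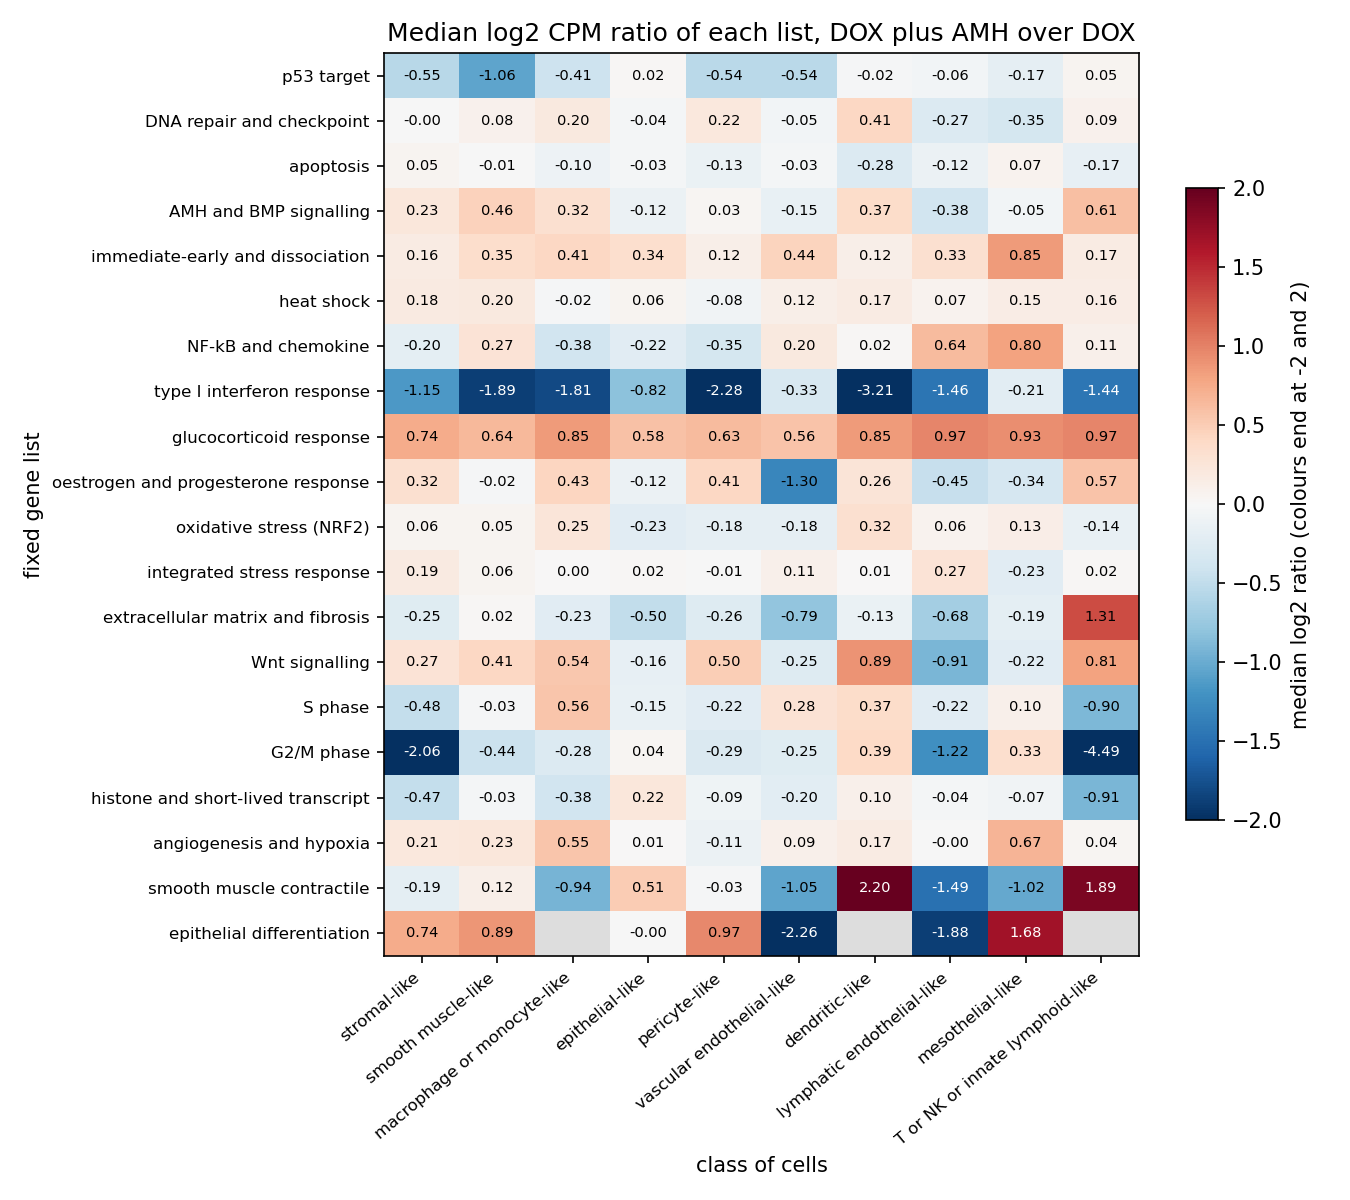
Median log2 ratio (DOX plus AMH over DOX, color scale) of each fixed gene list (vertical axis) in each class (horizontal axis), without error bars. The interferon list is below 0 in 10 of the 10 classes and the glucocorticoid list above 0 in 10 of the 10.

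In stromal-like cells, p53 targets, interferon-induced genes and genes of mitosis were lower in DOX plus AMH, while glucocorticoid-induced genes were higher. Of the 32 p53 targets measured, 18 were at least 1.3-fold lower and 3 at least 1.3-fold higher, with a median of -0.55 (-0.67 to -0.47). Bax, which promotes cell death at the mitochondrion, was 143 and 72.2 CPM (log2 ratio -0.98, -1.04 to -0.92), and Ccng1, cyclin G1, 86.8 and 46.9 CPM (log2 ratio -0.89, -0.96 to -0.82). Mdm2, the ligase that degrades p53, was 73.2 and 43.0 CPM (log2 ratio -0.77, -0.84 to -0.69), and Phlda3, which restrains AKT, 116 and 68.2 CPM (log2 ratio -0.77, -0.83 to -0.70). Ckap2, a spindle protein, was 70.1 and 17.5 CPM (log2 ratio -2.0, -2.12 to -1.89). Cdkn1a, the cell cycle inhibitor p21, was 174 and 85.0 CPM (log2 ratio -1.04, -1.09 to -0.98), but these levels lie under 0.2 times that of the class with the highest level, where free RNA can contribute. So do those of Gdf15, a secreted stress factor, at 26.3 and 8.11 CPM.

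Of 19 interferon list genes measured in stromal-like cells, 18 were at least 1.3-fold lower and 0 higher, with a median of -1.15 (-1.24 to -1.08). Ifit3, an interferon-induced antiviral protein, was 91.7 and 15.6 CPM (log2 ratio -2.55, -2.67 to -2.43), and its neighbour Ifit3b 26.3 and 4.61 CPM (log2 ratio -2.51, -2.73 to -2.29). The antiviral genes Rsad2 and Ifi44 were 32.2 and 2.75 CPM and 18.5 and 2.78 CPM. The NF-kB and chemokine list had a median of -0.20 (-0.34 to -0.17), with the chemokines Cxcl10 (91.0 and 23.9 CPM) and Ccl2 (49.5 and 15.1 CPM) lower. These 4 genes had levels under 0.2 times that of their highest class.

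Mitotic transcripts were lower in stromal-like cells of DOX plus AMH for 20 of the 20 G2/M genes measured, with a median of -2.06 (-2.17 to -1.9), and for 12 of 20 S phase genes, with a median of -0.48 (-0.61 to -0.40). Among the lowest genes of the class were the kinetochore genes Cenpe (-2.75, -3.03 to -2.48), Cenpf (-2.53, -2.69 to -2.38) and Cenpa (-2.22, -2.4 to -2.04), the spindle genes Hmmr (-2.48, -2.72 to -2.25) and Prc1 (-2.3, -2.44 to -2.15), and Diaph3 (-1.86, -2.01 to -1.7), Cdk1 (-1.8, -2.0 to -1.62) and Cks2 (-1.72, -1.88 to -1.56), given as log2 ratios. Several of these lead cluster 7, the dividing stromal-like cluster with 239 and 27 cells. At 2000 UMIs per cell, 2.99% (2.53 to 3.51) and 0.749% (0.494 to 1.09) of stromal-like cells held a UMI of Mki67, a marker of dividing cells, with 56 and 56 shallower cells left out. Without thinning the shares were 7.18% and 1.94%. Pericyte-like cells, which had Mki67 at 2.30 and 0.648 CPM, gave 0.453% and 0% at 2000 UMIs, at median depths of 9372 and 7610 UMIs against 14813 and 10188 in stromal-like cells. Without clusters 7, 11 and 23, the stromal-like difference was -0.717 percentage points, against -2.24 with them. Lymphocyte-like cells gave 16% (8.55 to 26.28) and 3.90% (0.811 to 10.97) at 2000 UMIs, on 12 and 3 cells with a UMI and with 2 and 5 cells left out. Unthinned they gave 24.7% and 9.76%. The intervals at 2000 UMIs overlap, so no difference is read from these shares. Epithelial-like cells gave 8.24% and 9.24%, with 3 and 4 left out, and 30% and 20.3% unthinned, so that no order is read there either.

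**Figure D3:**
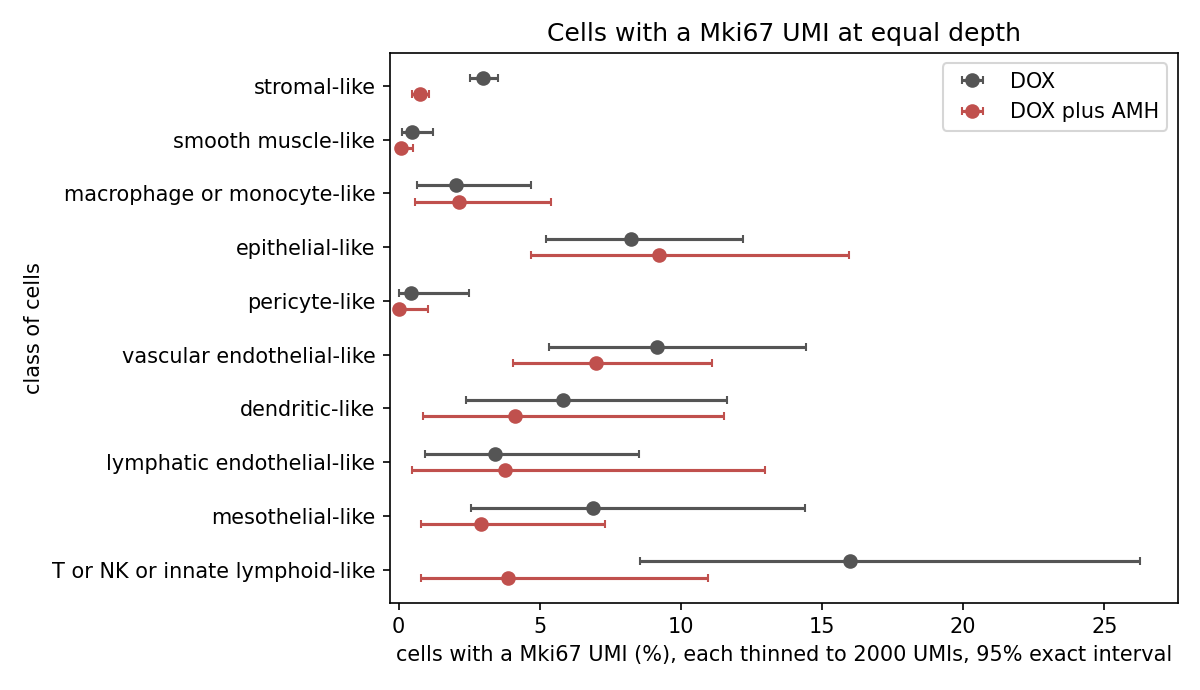
Share of cells with a Mki67 UMI at 2000 UMIs per cell (percent, horizontal axis) by class for DOX and DOX plus AMH, with exact 95% binomial intervals. Stromal-like cells were at 2.99% and 0.749% and lymphocyte-like cells at 16% and 3.90%, the latter with intervals that overlap.

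Of the 12 glucocorticoid response genes, 11 were at least 1.3-fold higher in stromal-like cells and 0 lower, with a median of 0.74 (0.67 to 0.84). Per1, a clock gene that glucocorticoids induce, was 7.76 and 15.9 CPM (log2 ratio 1.04, 0.87 to 1.2), and the sulfotransferase Sult1a1, under the free RNA limit, was 2.23 and 6.55 CPM. The highest genes of the class included the methyltransferase Inmt (2.15, 2.04 to 2.25), Coch (1.34, 1.26 to 1.41), Dtna (1.31, 1.21 to 1.4), Sntg1 (1.25, 1.17 to 1.33), the collagen Col25a1 (1.2, 1.07 to 1.33) and the IGF-binding protein Igfbp3 (1.29, 1.26 to 1.32), given as log2 ratios. Igfbp3 is among the leading genes of cluster 4, which held 2.93% and 5.44% of the kept cells, Inmt among those of clusters 5 and 15, and Sntg1 of cluster 12. Car3 and Cfd, genes that adipocytes express strongly, were 4.97 and 42.1 CPM and 29.7 and 108 CPM, beside higher adipocyte markers in the whole DOX plus AMH library, Adipoq (0.498 and 3.15 CPM) and Plin1 (0.332 and 1.67 CPM). With the stricter cell filter the log2 ratio of Cfd was -0.35. The unnamed loci Gm10800 (2.03, 1.88 to 2.17), Gm47283 (1.16, 1.12 to 1.2) and Gm26771 (1.14, 1.04 to 1.25) were also among the highest, and Apod, a lipocalin, among the lowest (-1.85). Gm10800 leads cluster 29, with 0 and 34 cells, which the free RNA limit does not cover.

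The median of the AMH and BMP signalling list in stromal-like cells was 0.23 (0.20 to 0.36), beside a median of 0.10 for all counted genes, and was 0.04 under TMM scaling. Id3, a BMP target, was 167 and 175 CPM, and under TMM scaling its log2 ratio was -0.12. The oestrogen and progesterone list had a median of 0.32 (0.25 to 0.38), with Ptch1, the hedgehog receptor, at 64.6 and 113 CPM (log2 ratio 0.81, 0.75 to 0.87). Wnt signalling genes had 0.27 (0.20 to 0.33), with the secreted Wnt modulator Sfrp2 at 73.4 and 128 CPM (log2 ratio 0.80, 0.75 to 0.86). The extracellular matrix list was lower at -0.25 (-0.34 to -0.18), with the basement membrane collagen Col4a1 at 311 and 190 CPM (log2 ratio -0.71, -0.75 to -0.67), and histone and short-lived transcripts had -0.47 (-0.54 to -0.40). The smooth muscle contractile list had -0.19 (-0.27 to -0.10), with the gap junction gene Gja1 at 96.3 and 57.5 CPM (log2 ratio -0.74, -0.81 to -0.68). Medians of the other lists were 0.16 for immediate-early genes, 0.18 for heat shock, 0.19 for the integrated stress response, 0.21 for angiogenesis, 0.06 for NRF2 targets, 0.05 for apoptosis and -0.0036 for DNA repair. Under TMM scaling those of immediate-early genes, heat shock, the integrated stress response, NRF2 targets and apoptosis lay below 0, at -0.02, -0.0089, -0.0037, -0.13 and -0.14. The epithelial differentiation list had 0.74, and its keratin gene Krt5 was counted 3 and 691 times (log2 ratio 8.76, 7.2 to 11.04), beside the keratin-rich cluster 24 of the same library. Over 6287 counted genes, 32 were at least 2-fold higher and 62 at least 2-fold lower, a count by size and not of significant genes. TMM scaling moved all ratios of the class by -0.19, to 17 higher and 100 lower, so that the lower share of both went from 66.0% to 85.5%.

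In smooth muscle-like cells, p53 targets were lower and targets of BMP-type signalling higher in DOX plus AMH. Of 31 p53 targets measured, 26 were at least 1.3-fold lower and 3 higher, with a median of -1.06 (-1.17 to -0.92). Cdkn1a was 671 and 285 CPM (log2 ratio -1.23, -1.3 to -1.17), Mdm2 111 and 46 CPM (log2 ratio -1.27, -1.43 to -1.12) and Ccng1 196 and 74.4 CPM (log2 ratio -1.4, -1.52 to -1.28). Bax was 267 and 124 CPM (log2 ratio -1.1, -1.2 to -1.01), Phlda3 255 and 111 CPM (log2 ratio -1.2, -1.3 to -1.1), Ckap2 96.9 and 18.8 CPM (log2 ratio -2.37, -2.59 to -2.15) and the kinase gene Plk2 21.3 and 6.05 CPM (log2 ratio -1.82, -2.23 to -1.41). Apaf1, which assembles the apoptosome, was 50.9 and 27.5 CPM (log2 ratio -0.89, -1.1 to -0.68), in an apoptosis list with a median of -0.01.

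**Figure D4:**
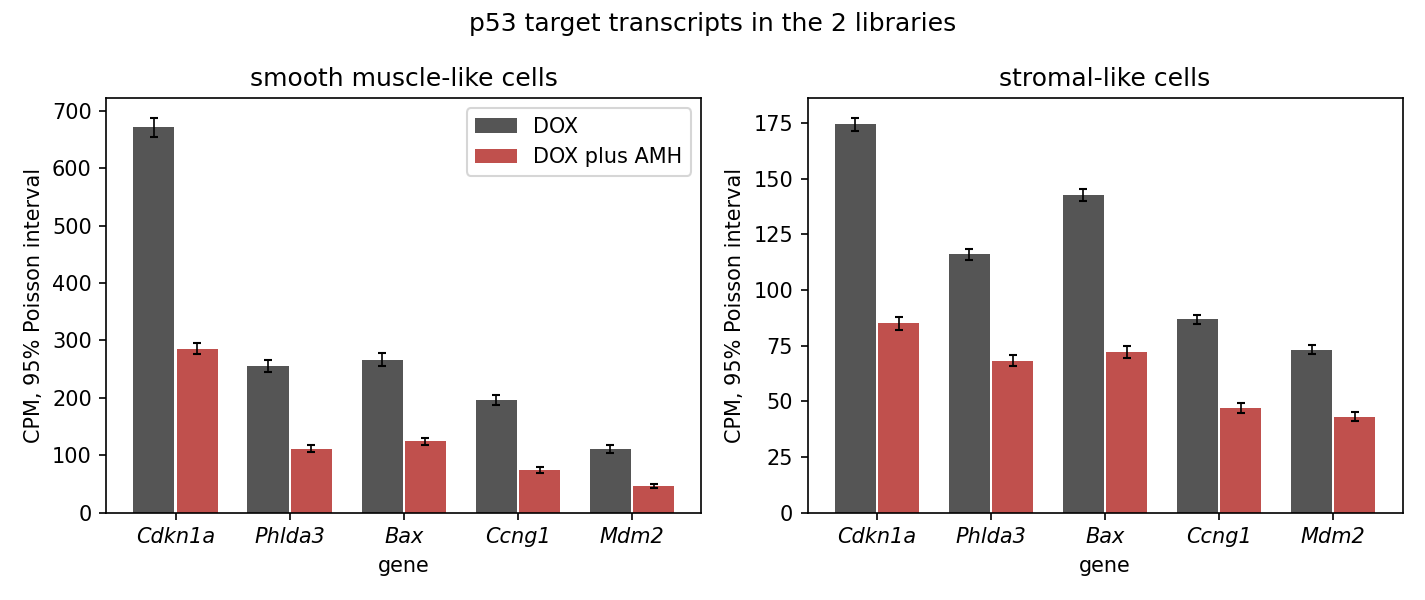
CPM (vertical axis) of p53 target genes in smooth muscle-like and stromal-like cells of DOX and DOX plus AMH, with 95% Poisson intervals as error bars. In smooth muscle-like cells Cdkn1a was at 671 and 285 CPM and Ccng1 at 196 and 74.4 CPM.

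Id1, Id2 and Id3, inhibitors of differentiation that BMP-type receptors induce through SMAD proteins, were higher in smooth muscle-like cells of DOX plus AMH. Id2 was 141 and 298 CPM (log2 ratio 1.08, 0.99 to 1.18) and Id3 109 and 337 CPM (log2 ratio 1.63, 1.53 to 1.73). Id1 was 17.6 and 53.5 CPM (log2 ratio 1.61, 1.35 to 1.86), just under the free RNA limit. Smad9, a SMAD of this pathway, was 2.25 and 10.2 CPM (log2 ratio 2.19, 1.51 to 2.93). Of 22 list genes measured, 11 were at least 1.3-fold higher and 2 lower, with a median of 0.46 (0.33 to 0.61). The receptor Amhr2 was highest in this class, at 9.85 (7.94 to 12.1) and 12.6 (10.6 to 14.9) CPM, and 8.11% and 8.97% of its cells held a UMI, at median depths of 10250 and 9058 UMIs. Blood-derived cells, which should lack the receptor, gave 0.413% and 0.536% at median depths of 7820 and 8723 UMIs. Stromal-like cells had Amhr2 at 0.925 (0.721 to 1.17) and 0.918 (0.646 to 1.26) CPM, and mesothelial-like cells at 1.74 (0.475 to 4.46) and 4.10 (2.24 to 6.88) CPM.

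The smooth muscle-like class held cluster 8 (Acta1, Tnni2, Pcp4) with 456 and 587 cells and cluster 16 (Actg2, Scx, Cnn1) with 444 and 539. Amhr2 was 16.6 (13.2 to 20.7) and 21.3 (17.6 to 25.6) CPM in cluster 8 and 2.83 (1.51 to 4.85) and 4.49 (2.93 to 6.58) CPM in cluster 16. Log2 ratios in cluster 8 were 2.05 (1.74 to 2.37) for Id1, 1.55 (1.42 to 1.68) for Id2 and 2.35 (2.21 to 2.5) for Id3. In cluster 16 they were 0.59 (0.14 to 1.06), 0.56 (0.42 to 0.69) and 0.65 (0.50 to 0.80). Smad9 had 3.39 (2.2 to 4.88) in cluster 8 and 1.18 (0.31 to 2.14) in cluster 16. Cdkn1a was lower in both, at -2.54 (-2.76 to -2.32) and -1.14 (-1.21 to -1.07). Immediate-early genes, which dissociation also induces, differed in the same order, with medians of 0.52 (0.41 to 0.75) in cluster 8 and 0.20 (0.09 to 0.35) in cluster 16, and Fos was 1.19 (1.04 to 1.34) and 0.10 (0.01 to 0.20).

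**Figure D5:**
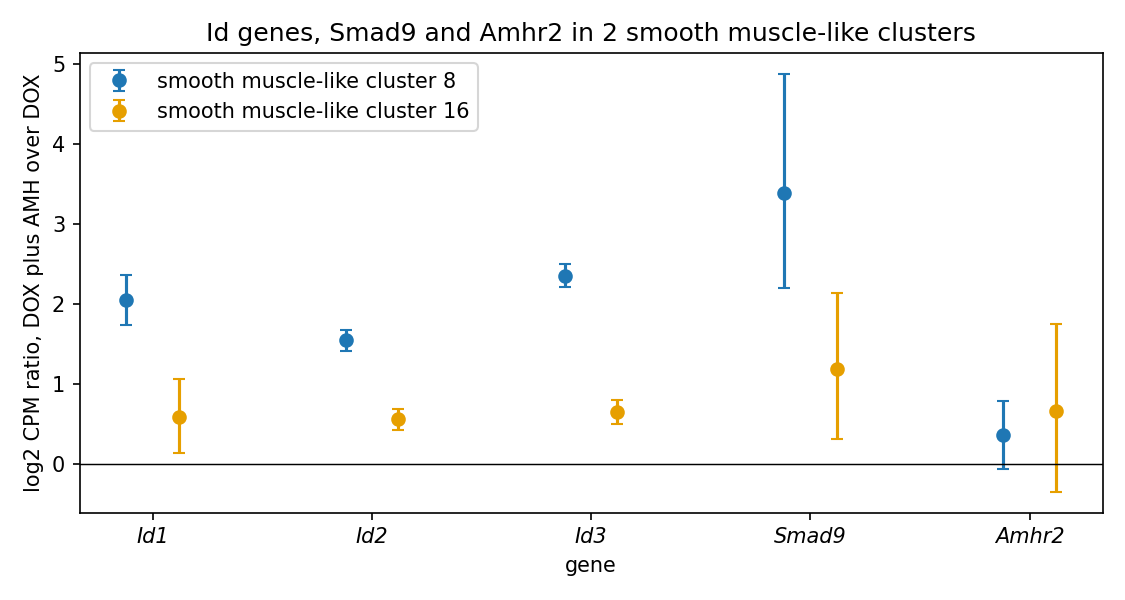
Log2 ratio (DOX plus AMH over DOX, vertical axis) of Id1, Id2, Id3, Smad9 and Amhr2 in smooth muscle-like clusters 8 and 16, with 95% counting intervals. Id3 had 2.35 in cluster 8, where Amhr2 was higher, and 0.65 in cluster 16.

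Interferon genes were also lower in smooth muscle-like cells, at least 1.3-fold for 18 of 19, with a median of -1.89 (-2.17 to -1.73), and the glucocorticoid list was higher at 0.64 (0.54 to 0.79). Greb1, an oestrogen target, was 109 and 39.5 CPM (log2 ratio -1.47, -1.63 to -1.3), in an oestrogen and progesterone list with 6 genes higher and 6 lower of 16 and a median of -0.02 (-0.14 to 0.21), and the ligand gene Wnt4 45.7 and 14.2 CPM (log2 ratio -1.69, -1.96 to -1.43). The Wnt list had a median of 0.41 (0.21 to 0.49), with the Wnt modulator Dkk2 at 23.4 and 55.2 CPM (log2 ratio 1.24, 1.01 to 1.47). Ccn1, a matricellular protein, was 12.1 and 42 CPM (log2 ratio 1.79, 1.5 to 2.1), and the chaperone Hspa1b 88.9 and 190.5 CPM (log2 ratio 1.1, 0.98 to 1.22). The highest genes were the tight junction gene Cldn1 (4.66, 3.66 to 5.89), the homeobox genes Hoxa5 (2.44, 1.93 to 2.99), Hoxc8 (2.34, 1.92 to 2.78) and Cux2 (2.09, 1.72 to 2.49), and Gm14226 (2.3, 1.89 to 2.74), and among the lowest, beside Ckap2, were 1700007K13Rik (-2.91, -3.38 to -2.46), Sncg (-2.82, -3.21 to -2.44) and Plcd4 (-2.72, -3.25 to -2.23), given as log2 ratios. Squamous keratin genes were higher in this class too, with Krt5 counted 4 and 190 times and Krt14 0 and 109 times. The epithelial differentiation list had a median of 0.89 (0.37 to 1.15), with 5 of 9 genes higher and 2 lower. These values stand beside the keratin-led cluster of the DOX plus AMH library. Whether free RNA from that cluster adds to Cldn1 was not tested. Contractile genes differed little, with a median of 0.12 (0.09 to 0.17) that was -0.01 under TMM scaling. Over 6472 counted genes, 60 were at least 2-fold higher and 80 lower, and under TMM scaling, which moved the ratios by -0.13, 36 and 118, so that the lower share of both went from 57.1% to 76.6%.

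In macrophage or monocyte-like cells, interferon-induced genes were far lower in DOX plus AMH and the arginase gene Arg1 far higher. Arg1, an enzyme of alternatively activated macrophages, was 2.35 and 1169 CPM (log2 ratio 8.96, 7.83 to 10.41). Saa3, an acute-phase protein, was 7.05 and 835 CPM (log2 ratio 6.89, 6.22 to 7.65), the ribonuclease gene Rnase2a 1.96 and 331 CPM (log2 ratio 7.4, 6.17 to 9.03) and the arginine transporter gene Slc7a2 3.92 and 176 CPM (log2 ratio 5.49, 4.6 to 6.56). The scavenger receptor gene Marco, with 2 UMIs in DOX, had a log2 ratio of 7.28 (5.42 to 10.33), and Fn1, fibronectin, was 181 and 1422 CPM (log2 ratio 2.98, 2.83 to 3.12). Cxcl10, an interferon-induced chemokine, was 643 and 12.9 CPM (log2 ratio -5.64, -6.2 to -5.14), Ifit3 448 and 12.9 CPM (log2 ratio -5.12, -5.68 to -4.62), Ifit2 262 and 9.65 CPM (log2 ratio -4.76, -5.41 to -4.17) and Ifit3b 109.7 and 1.61 CPM (log2 ratio -6.09, -7.98 to -4.72). Ifit1bl1, with 2 UMIs in DOX plus AMH, had a log2 ratio of -7.24 (-10.29 to -5.38). The interferon list had a median of -1.81 (-1.89 to -1.72), the NF-kB list -0.38 (-0.70 to -0.22) and the p53 list -0.41 (-0.53 to -0.31). Lists of dissociation and of other cells differed as well. Immediate-early genes had a median of 0.41 (0.31 to 0.52), and 8 of 12 contractile genes were lower, at -0.94 (-1.11 to -0.58). Over 6110 counted genes, 140 were at least 2-fold higher and 206 lower, and TMM scaling moved the ratios by -0.11 and the lower share of both from 59.5% to 72.5%.

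In mesothelial-like cells, Cxcl2, Serpina3n and Mt2 were among the genes higher in DOX plus AMH. The neutrophil chemokine gene Cxcl2, with 3 UMIs in DOX, had a log2 ratio of 7.29 (5.74 to 9.57). Serpina3n, an acute-phase protease inhibitor, was 3.05 and 261 CPM (log2 ratio 6.42, 5.37 to 7.74). Mt2, a metallothionein that glucocorticoids induce, was 35.7 and 426 CPM (log2 ratio 3.58, 3.25 to 3.91). Hsd11b1, which regenerates active glucocorticoid, had 0 UMIs in DOX and was at least 54.2-fold higher against a floor of 3 counts. Tdo2, with 2 UMIs in DOX, had 5.54 (3.65 to 8.6), and thinning to 2000 UMIs per cell left 0 and 3 UMIs, too few to read. Egln3, an oxygen sensor, was 13.1 and 112 CPM (log2 ratio 3.1, 2.56 to 3.69), and Sod2, a mitochondrial superoxide dismutase, 113 and 289 CPM (log2 ratio 1.36, 1.16 to 1.56). Id1, Id2 and Id3 were 58.4 and 122 CPM (log2 ratio 1.06, 0.78 to 1.35), 27.9 and 88.4 CPM (log2 ratio 1.67, 1.27 to 2.08) and 118 and 274 CPM (log2 ratio 1.22, 1.02 to 1.42).

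Col6a5 was also among the highest genes but helps to define the mesothelial-like cluster, and is not read as a difference. The lowest genes were Xpnpep2 (-2.91, -3.53 to -2.34), Col4a1 (-2.41, -2.66 to -2.16), Nkain2 (-2.4, -2.67 to -2.13), A230057D06Rik (-2.38, -2.88 to -1.9) and P2rx7 (-2.29, -2.85 to -1.76), as log2 ratios. Cdkn1a was 835 and 884 CPM and the p53 list had a median of -0.17 (-0.31 to -0.10). Of the 17 NF-kB and chemokine genes measured, 11 were at least 1.3-fold higher and 1 lower, with a median of 0.80 (0.65 to 1.14). Lists of dissociation and of other cells differed in this class too, with 17 of 24 immediate-early genes higher, at 0.85 (0.78 to 0.92), 7 of 7 epithelial differentiation genes higher, at 1.68 (1.01 to 2.02), and 10 of 12 contractile genes lower, at -1.02 (-1.31 to -0.89). Over 7170 counted genes, 253 were at least 2-fold higher and 238 lower, and TMM scaling moved the ratios by 0.15 and the lower share of both from 48.5% to 33.6%.

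In epithelial-like cells, Ovgp1 was higher and Sprr2f and Lcn2 lower in DOX plus AMH. Ovgp1, oviductal glycoprotein, was 17.6 and 356 CPM (log2 ratio 4.33, 4.14 to 4.54). Calb1, a calcium-binding protein, was 48.7 and 234 CPM (log2 ratio 2.26, 2.13 to 2.4), Rtn1 (5.54, 4.59 to 6.69), Cntnap3 (2.38, 2.02 to 2.76) and Sox1ot (2.28, 1.94 to 2.62) were also among the highest, as log2 ratios. Sprr2f, a cornified envelope gene that oestrogen induces, was 123 and 16.6 CPM (log2 ratio -2.88, -3.17 to -2.61), and Lcn2, lipocalin 2, 379 and 104 CPM (log2 ratio -1.86, -1.98 to -1.75). Of the 16 oestrogen and progesterone response genes measured, 6 were at least 1.3-fold lower and 1 higher, with a median of -0.12 (-0.33 to -0.06). The genes St6gal1 (-2.17, -2.5 to -1.86), Cfi (-2.1, -2.48 to -1.75) and Mcub (-2.08, -2.49 to -1.69) were also among the lowest. Sprr1a, at 25.9 and 4.41 CPM, had log2 ratios of opposite sign with the stricter filter (5.09) and with each library clustered on its own (3.12). Sprr1a is among the leading genes of cluster 24, and its UMIs in the class were 319 and 13115, and 455 and 4870, under these settings. The epithelial-like share turned to 2.03 and 3.86 percentage points there, and was 4.66 with clusters 24 and 27 counted as epithelial-like. Whether cells of cluster 24 joined the class was not tested, so these sign changes are not read as changes within epithelial-like cells. Markers of ciliated oviduct cells were higher over all cells of the same library, Tmem212 (0.140 and 10.5 CPM), Foxj1 (0.297 and 3.55 CPM) and Ccdc153 (0.0699 and 7.40 CPM). Interferon genes had a median of -0.82 (-1.15 to -0.60) and p53 targets 0.02 (-0.12 to 0.08). The summed interferon list differed far less, at 2229 and 2091 CPM (log2 ratio -0.09, -0.12 to -0.06). At 2000 UMIs per cell, 82.8% and 79.8% of these cells held at least 3 UMIs of the interferon list. Over 6919 counted genes, 57 were at least 2-fold higher and 81 lower.

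In vascular endothelial-like cells, Cfd, Retn, Scd1 and Car3 were higher in DOX plus AMH. The adipokine genes Cfd and Retn were 9.22 and 382 CPM (log2 ratio 5.37, 4.85 to 5.94) and 2.15 and 59.3 CPM (log2 ratio 4.78, 3.72 to 6.11), the desaturase gene Scd1 6.15 and 138 CPM (log2 ratio 4.49, 3.85 to 5.22), Car3 14.8 and 171 CPM (log2 ratio 3.54, 3.12 to 3.99) and Gm11290 4.00 and 27.6 CPM (log2 ratio 2.79, 1.95 to 3.74). They stand beside adipocyte markers that were higher over all cells of that library, Cidec (0.227 and 2.10 CPM) and Retn (1.97 and 8.98 CPM). In the class itself Adipoq was 0.615 and 17.0 and Plin1 0.615 and 7.09 CPM. Fos, an immediate-early gene, was 207 and 497 CPM (log2 ratio 1.26, 1.13 to 1.39), Sgk1, a glucocorticoid-induced kinase, 51.0 and 109.9 CPM (log2 ratio 1.11, 0.84 to 1.37) and Id3 466 and 788 CPM (log2 ratio 0.76, 0.67 to 0.85). All cells of this class in DOX plus AMH lay in cluster 20 (Fabp4, Flt1, Scarb1), which held 130 and 243 cells, while cluster 11 held 70 and 0. The DOX values of the higher genes above include cluster 11, so the size of their ratios is not read as a change within endothelial-like cells alone. In cluster 20 the immediate-early list had a median of 0.25 (0.15 to 0.39) and the glucocorticoid list 0.59 (0.32 to 0.83). The lowest genes were Sema3e (-5.41, -7.05 to -4.16), Chst9 (-5.23, -6.88 to -3.98) and Lgr5 (-4.94, -6.58 to -3.67), with Lrrc31 at -6.13 (-9.19 to -4.24) on 2 UMIs in DOX plus AMH and Gm29904 at -5.33 (-7.63 to -3.73) on 3. Without cluster 11, Sema3e and Chst9 were each left with 1 and 5 UMIs, so their lower levels rest on that cluster. Of 7344 counted genes, 82 were at least 2-fold higher and 412 lower, and without clusters 7, 11 and 23 the counts of genes at least 2-fold apart in vascular endothelial-like cells were 67 higher and 47 lower. Epithelial markers in the class were lower as well, with Epcam at 90.1 and 6.08, Wfdc2 at 292 and 17.5 and Pax8 at 28.6 and 2.28 CPM. Without clusters 7, 11 and 23 the median of the epithelial differentiation list in the class went from -2.26 to 1.66. The lower epithelial markers therefore cannot be told apart from the absence of cluster 11 in DOX plus AMH, and are not read as a change within endothelial-like cells.

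In dendritic-like cells the interferon list had its lowest median, -3.21 (-3.74 to -2.74), while the DNA topoisomerase gene Top2a was 97.9 and 166 CPM (log2 ratio 0.76, 0.44 to 1.09) and Bax 548 and 313 CPM (log2 ratio -0.81, -1.0 to -0.62). The smooth muscle contractile list, made of markers of another class, was higher there for 9 of 9 genes, with a median of 2.2 (1.77 to 2.45). Over the 10 classes the interval of this list lay above 0 in 4 and below 0 in 5. 66 of 3416 counted genes were at least 2-fold higher and 138 lower, and TMM scaling moved the ratios by -0.13 and the lower share of both from 67.7% to 81.3%. In lymphocyte-like cells Mki67 was 249.7 and 16.4 CPM (log2 ratio -3.92, -5.08 to -2.95) and Top2a 396 and 21.9 CPM (log2 ratio -4.17, -5.15 to -3.34), with a G2/M median of -4.49 (-5.93 to -4.37). Without thinning, 19 of 77 and 8 of 82 cells held a Mki67 UMI, or 24.7% (15.6 to 35.8) and 9.76% (4.31 to 18.3), and these intervals overlap. The ratios thus rest on few cells, and their intervals leave out the spread between cells. The contractile list in lymphocyte-like cells was higher for 8 of 8 genes, at 1.89 (1.4 to 2.42). There 23 of 1560 counted genes were at least 2-fold higher and 45 lower. In pericyte-like cells Phlda3 was 90.1 and 29.8 CPM (log2 ratio -1.6, -1.97 to -1.23) and Bax 185 and 79.3 CPM (log2 ratio -1.22, -1.46 to -0.99), with a p53 median of -0.54 (-0.69 to -0.31) and an interferon median of -2.28 (-2.68 to -1.93). Here 40 of 6420 counted genes were at least 2-fold higher and 56 lower. In lymphatic endothelial-like cells Cdkn1a was 604 and 704 CPM (log2 ratio 0.22, 0.09 to 0.36) and Mdm2 239 and 162 CPM (log2 ratio -0.56, -0.83 to -0.30). Lists of other cells differed here too. The contractile list was lower for 9 of 11 genes, at -1.49 (-1.74 to -1.1), and the epithelial differentiation list for 3 of 3, at -1.88 (-3.19 to -1.22). Of this class, cluster 17 (Ccl21a, Mmrn1) held 78 and 55 cells and cluster 23 41 and 1, and 72 of 5341 counted genes were at least 2-fold higher and 173 lower.

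Markers of cells outside the compared classes differed between the libraries as well. Haemoglobin genes of red cells were higher in DOX plus AMH, Hbb-bs (75.6 and 1600 CPM) and Hba-a1 (21.4 and 453 CPM), as were the B cell genes Ighm (5.08 and 34.3 CPM) and Cd79a (0.323 and 1.55 CPM) and the neutrophil genes S100a8 (0.594 and 7.70 CPM) and S100a9 (0.917 and 6.66 CPM), though not Ly6g (0.349 and 0.101 CPM). Of granulosa cell markers, Inha was 2.01 and 3.07 CPM and Foxl2, which uterine stroma also expresses, 35.5 and 25.3 CPM. Of mast cell markers, Hdc was 6.35 and 13.4 CPM and Cpa3 0.183 and 0.224 CPM. On the mm10 build, Cdkn1a (ENSMUSG00000023067) on chromosome 17, 29090976 to 29100727 is annotated as a protein-coding gene, as are Mdm2 (ENSMUSG00000020184) on chromosome 10, 117688875 to 117710758, Id1 (ENSMUSG00000042745) on chromosome 2, 152736251 to 152737410, Id2 (ENSMUSG00000020644) on chromosome 12, 25093799 to 25097140, Id3 (ENSMUSG00000007872) on chromosome 4, 136143497 to 136145755. The rest are Ifit3 (ENSMUSG00000074896) on chromosome 19, 34583531 to 34588731, Amhr2 (ENSMUSG00000023047) on chromosome 15, 102445367 to 102454633, Arg1 (ENSMUSG00000019987) on chromosome 10, 24915221 to 24927484, and Mki67 (ENSMUSG00000031004) on chromosome 7, 135689784 to 135716361.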

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

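Tests of the cluster mix, of depth in smooth muscle-like cells, of free RNA, of cells with 3 interferon UMIs, of adjacent tissue and of clusters 8 and 16 were chosen after the results they address were seen, and the depth tests in stromal-like cells, the 1-UMI test, the Hoxa13 test and the test within cluster 8 before. Some replaced earlier forms after those had been run. For interferon, free RNA was first judged by CPM, where stromal-like cells of DOX had 3497 CPM of the list against 2005 in lymphocyte-like cells, a ratio of 1.74 that decided nothing between bounds of 1.5 and 3. For p53 targets the same question by CPM gave 24 of 26 members, and UMIs per cell, with a raised bound, took its place. The cluster test first took both classes together, with 7 of 10 clusters, which decided nothing, was then split by class, and in stromal-like cells was later given a second form that sets each cluster against random lists. Both free RNA tests were later repeated with the mean depth of DOX plus AMH scaled to that of DOX, which leaves the spread of depths as it was, with their bounds kept.

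The first pattern is the lower p53 target transcripts in DOX plus AMH. The depth gap does not explain it, since the list's median was -0.91 (-1.09 to -0.72) in stromal-like cells of 8000 to 12000 UMIs, 916 and 1391 cells, and -0.97 (-1.06 to -0.77) in smooth muscle-like cells of that depth, 374 and 442 cells. The stromal-like window takes the shallower cells of DOX, as the class medians were 14813 and 10188 UMIs, and so does not hold the mix of clusters equal. With stromal-like cells thinned to 2000 UMIs the list's median was -0.77. With all smooth muscle-like cells thinned to 2000 UMIs it was -1.1, and free RNA falls short, since for 22 of the 26 members lower in smooth muscle-like cells the loss per cell exceeded the DOX mean of the class with the lowest mean, and likewise for 22 with mean depths scaled alike. Another mix of clusters is argued against in smooth muscle-like cells, where 2 of the 2 clusters had medians below -0.2. In stromal-like cells the list lay at or below the 2.5 percentile of random lists in 7 of the 8 clusters. That form decides nothing, since clusters 0 (-0.08, -0.26 to 0.05) and 3 (-0.26, -0.36 to 0.01) passed it with intervals that held 0. The mix as the whole cause there is argued against by clusters 5 (-0.52, -0.67 to -0.31), 9 (-0.81, -0.96 to -0.69) and 12 (-0.31, -0.42 to -0.25). With each cluster weighted alike the median was -0.33, though cluster 15 was at 0.25 (-0.02 to 0.40). As a part of the cause the mix cannot be told apart, since medians lay below -0.2 in 5 of the 8 and ran from -0.81 to 0.25. A response to the hormone stays open as a hypothesis, untested, as do pools of other animals and how each pool was handled, which are confounded with the groups.

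The second pattern is the lower type I interferon transcripts. The depth gap does not explain it, since the list's median was -0.90 (-1.07 to -0.74) in stromal-like cells of 8000 to 12000 UMIs, a window with the limit given above. It also lay between -1.335 and -1.129 over all settings run, thinning to 2000 UMIs among them. Free RNA falls short, since the loss of 35.5 UMIs per stromal-like cell was 2.66 times the 13.3 in DOX lymphocyte-like cells, the class with the lowest mean, and 2.08 times (1.54 to 2.93) with the mean depth of DOX plus AMH scaled to that of DOX, since the first value includes the depth gap, against a bound of 1.5. The share of stromal-like cells with at least 1 list UMI at 2000 UMIs was 95.7% and 89.8%, a difference of -5.82 percentage points that leaves a few very high cells open, since the intervals are apart but their ends lie closer than the bound of 5 points set beforehand, while with at least 3 it was 69.4% and 48.7%, or -20.7 points, against that explanation. A response to the hormone stays open, untested, as does an interferon response to something else in the DOX pool, since pools and groups are confounded and no untreated library was analysed here.

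The third pattern is a signal outside the classes compared. The keratin-led cluster 24 held 0.0954% and 7.21% of the cells, and Adipoq of adipocytes was 0.498 and 3.15 CPM. Adipocyte markers were at least 2-fold higher for 4 of the 5, all but Lep with 8 and 3 UMIs, as tissue from next to the uterine horns in the DOX plus AMH pool would give, yet Hoxa13, which cervix and vagina express, was at 0 CPM in cluster 24, with an upper bound of 0.274. So adjacent tissue cannot be told apart from uterine epithelial cells in another state, and Hoxa13 decides little, since it was at 0 in the epithelial-like cluster 6 as well. Other pieces of tissue may have entered 1 pool, and a biological difference stays open as untested.

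Other signals outside the comparisons were the red cell gene Hbb-bs at 75.6 and 1600 CPM, the ciliated cell gene Tmem212 at 0.140 and 10.5 CPM, and the B and plasma cell gene Igkc, with 3 UMIs in DOX and 7564 in DOX plus AMH, or 84.6 CPM. Log2 ratios of Top2a had opposite signs in 2 classes, at 0.76 in dendritic-like and -4.17 in lymphocyte-like cells. The difference of 4.94 was not tested. At 2000 UMIs per cell, 10 and 8 dendritic-like cells held a Top2a UMI, or 8.33% (4.07 to 14.79) and 10.96% (4.85 to 20.46). In lymphocyte-like cells 12 and 3 did, or 16% (8.55 to 26.28) and 3.90% (0.811 to 10.97). The intervals overlap in both classes, so no opposite difference is read from these shares.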

How the results depend on the processing

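The settings that weight each cluster alike, leave out clusters 7, 11 and 23, count clusters 24 and 27 as epithelial-like or leave out cluster 24 were chosen after seeing the data. The text names fewer genes than its rule allows, shortened by rank after all had been run, and both counts are given. An earlier set picked by hand, which held fewer genes whose sign changed beyond counting error, was dropped for that reason. Of the alternative values, 47 of 3668 for the genes used changed sign from a main value beyond counting error and 1.3-fold, against 125 of 6902 for all genes of the rule. Of the 47, 32 had an interval that held 0 under the alternative and 19 rested on fewer than 10 UMIs in a library, as did Tdo2 in mesothelial-like cells, with 0 and 3 UMIs after thinning, and these are not read as reversals. The direction was the same for 3546 of the 3668 gene values (6653 of the 6902 for all), 2197 of 2460 list medians, 75 of 79 shares, 29 of 33 Amhr2 ratios and 125 of 156 Mki67 or Top2a shares. A further 656 gene values and 413 list medians lay outside the main interval, and 25 list medians and 3 shares changed sign from a main value beyond counting error, which for the lists was also at least 1.3-fold. Of 274 counts of genes, 91 moved by over 1.5 times, 20 of them under the 1.5-fold bound, which counts more genes by definition. The direction was the same under every setting run for the p53 list in smooth muscle-like (-1.19 to -0.99) and stromal-like cells (-0.77 to -0.33), the interferon list in stromal-like cells (-1.33 to -1.13), the glucocorticoid list in stromal-like cells (0.55 to 0.85), the AMH and BMP list in smooth muscle-like cells (0.26 to 0.50) and Amhr2 there (0.23 to 0.53). The CPM intervals of Amhr2 in that class overlapped, at 7.94 to 12.1 and 10.6 to 14.9, so no higher level of the receptor is read.

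The following values moved beyond counting error or changed sign from a main value beyond it, each followed by its main value in brackets, as log2 ratios for genes and lists and percentage points for shares. The cause was not tested. With no cell filter, values were the share 2.84 (4.43) in smooth muscle-like cells, the share -8.61 (-12.2) in stromal-like cells, the matrix list -0.00097 (1.31) in lymphocyte-like cells and the oestrogen and progesterone list -0.86 (0.41), the Wnt list -0.71 (0.50), the epithelial differentiation list -2.13 (0.97) in pericyte-like cells. With the stricter filter, values were the share 2.03 (-1.86), Sprr1a 5.09 (-2.55), Id2 -0.12 (0.42), Cdkn1a 1.33 (-0.98), Fancd2 -0.35 (0.73), Nusap1 -0.38 (0.64), Hist1h2ap -0.24 (0.85) in epithelial-like cells and the share 5.85 (4.43) in smooth muscle-like cells. There too, the share -14.9 (-12.2), Cfd -0.35 (1.86) in stromal-like cells differed. With doublets kept, values were the share -2.44 (-1.86), Icam1 -0.15 (0.64), Des -0.46 (1.16), the smooth muscle contractile list -0.84 (0.51) in epithelial-like cells, the matrix list -0.51 (1.31) in lymphocyte-like cells and the interferon list -1.71 (-1.81), the oestrogen and progesterone list -0.22 (0.43) in macrophage-like cells. There too, the AMH and BMP list 0.26 (0.46) in smooth muscle-like cells and the smooth muscle contractile list 0.22 (-1.05) in vascular endothelial-like cells differed. At Leiden resolution 0.5, values were the share -2.46 (-1.86) in epithelial-like cells, Id2 -0.0056 (0.66), the interferon list -1.92 (-1.81) in macrophage-like cells and the oestrogen and progesterone list -1.41 (0.41), the Wnt list -0.59 (0.50), the epithelial differentiation list -2.91 (0.97) in pericyte-like cells. There too, Sema3e 1.16 (-5.41), Chst9 1.16 (-5.23), Id2 0.79 (-0.57), Msx1 0.37 (-3.59), Padi1 0.95 (-3.45), Slc7a11 0.64 (-4.04), Myocd 0.50 (-2.62), the oestrogen and progesterone list 0.083 (-1.3), the epithelial differentiation list 1.66 (-2.26), the smooth muscle contractile list 0.17 (-1.05) in vascular endothelial-like cells differed. With each library clustered on its own, values were the share 3.86 (-1.86), Sprr1a 3.12 (-2.55), Id2 -0.14 (0.42), Cdkn1a 0.54 (-0.98), Apaf1 0.11 (-0.60), the matrix list 1.07 (-0.50) in epithelial-like cells and the matrix list -0.22 (1.31) in lymphocyte-like cells. There too, the interferon list -1.97 (-1.81) in macrophage-like cells differed. Under TMM scaling, values were the interferon list -1.92 (-1.81) in macrophage-like cells and the p53 list -1.19 (-1.06), the AMH and BMP list 0.33 (0.46), the count of higher genes 36 (60) in smooth muscle-like cells. There too, the p53 list -0.74 (-0.55), the interferon list -1.33 (-1.15), the glucocorticoid list 0.55 (0.74), the count of higher genes 17 (32), the count of lower genes 100 (62) in stromal-like cells differed.

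With CPM over nuclear genes alone, values were the count of lower genes 121 (80) in smooth muscle-like cells and the count of lower genes 98 (62) in stromal-like cells. With each cell weighted alike, values were Dtl 0.037 (-0.44) in epithelial-like cells, the NF-kB list -0.041 (0.64) in lymphatic endothelial-like cells and the interferon list -1.97 (-1.81) in macrophage-like cells. With cells thinned to 2000 UMIs, values were Gdf15 0.43 (-1.38), Acvr1 0.088 (-0.68), Wnt7b 0.58 (-1.25) in epithelial-like cells and Mki67 0.73 (-1.38), Top2a 0.28 (-1.79), the NF-kB list -0.29 (0.64), the G2/M phase list 0.038 (-1.22) in lymphatic endothelial-like cells. There too, the interferon list -2.13 (-1.81) in macrophage-like cells, Tdo2 -0.66 (5.54), Hist1h2ap -0.47 (1.02) in mesothelial-like cells, the count of lower genes 42 (80) in smooth muscle-like cells and Nqo1 -0.40 (0.42), the p53 list -0.77 (-0.55), the glucocorticoid list 0.85 (0.74) in stromal-like cells differed. There too, Pcna -0.020 (0.59) in vascular endothelial-like cells differed. With a 1.5-fold bound, values were the count of higher genes 319 (60), the count of lower genes 212 (80) in smooth muscle-like cells and the count of higher genes 180 (32), the count of lower genes 169 (62) in stromal-like cells. Without thinning, the value was the Mki67 share -5.24 (-2.24) in stromal-like cells. At 4000 UMIs per cell, the value was the Mki67 share -2.95 (-2.24) in stromal-like cells. With each cluster weighted alike, values were Actg2 0.53 (-0.61), the p53 list -0.33 (-0.55) in stromal-like cells and Sema3e 1.16 (-5.41), Chst9 1.16 (-5.23), Id2 0.79 (-0.57), Msx1 0.37 (-3.59), Padi1 0.95 (-3.45), Slc7a11 0.64 (-4.04), Myocd 0.50 (-2.62), the oestrogen and progesterone list 0.083 (-1.3), the epithelial differentiation list 1.82 (-2.26), the smooth muscle contractile list 0.17 (-1.05) in vascular endothelial-like cells. Without clusters 7, 11 and 23, values were Actg2 0.46 (-0.61), the Mki67 share -0.717 (-2.24) in stromal-like cells and Sema3e 1.16 (-5.41), Chst9 1.16 (-5.23), Id2 0.79 (-0.57), Msx1 0.37 (-3.59), Padi1 0.95 (-3.45), Slc7a11 0.64 (-4.04), Myocd 0.50 (-2.62), the oestrogen and progesterone list 0.083 (-1.3), the epithelial differentiation list 1.66 (-2.26), the smooth muscle contractile list 0.17 (-1.05) in vascular endothelial-like cells. With clusters 24 and 27 counted as epithelial-like, the value was the share 4.66 (-1.86) in epithelial-like cells. Without cluster 24, values were the share 5.71 (4.43) in smooth muscle-like cells and the share -8.03 (-12.2) in stromal-like cells.

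No paired analysis was possible because both groups hold a single pool of different animals, numbered 1 in each. Where a class fell below 50 cells in a library under a setting, or a gene was not measured, no value was given. Depth limits the smallest classes, with 512675 UMIs in lymphocyte-like cells of DOX.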

Other observations

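The test of Id genes between clusters 8 and 16, and the other cells set beside it, were chosen after the result was seen, the test within cluster 8 before. Stromal-like clusters differed in how far the interferon and glucocorticoid lists lay from 0. Cluster 12 (Bmper, Sntg1, with the inflammatory genes Il6, Cxcl1 and Tnfaip6) had an interferon median of -2.27 (-2.42 to -1.92) and cluster 9 (Col14a1, Mgp) -1.8 (-1.95 to -1.64), against -0.31 (-0.50 to -0.23) in cluster 0 (Cxcl14, A2m). Cluster 4 (Grm7, Igfbp3) had the highest glucocorticoid median among the stromal-like clusters measured, at 1.39 (0.88 to 1.61), against 0.47 (0.34 to 0.74) in cluster 0. The AMH and BMP list had 0.59 (0.48 to 0.74) in cluster 9 and 0.18 (0.13 to 0.31) in cluster 0. Cluster 12 differed from the class in immediate-early genes, at -0.23 (-0.26 to -0.13) against 0.41 (0.30 to 0.45) in cluster 9. The p53 list ran from -0.81 (-0.96 to -0.69) in cluster 9 to 0.25 (-0.02 to 0.40) in cluster 15 (Gm26802, Fosb).

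In DOX plus AMH, cells of cluster 24 had Krt5 at 4391 CPM, Krt14 at 2897, Trp63, a basal cell regulator, at 462, and the Müllerian gene Pax8 at 78.5, against 17.8, 8.53, 5.15 and 144 CPM in cluster 6, led by Fxyd4 and Wfdc2. Hoxa10, a gene of the uterus, was 9.64 and 4.56 CPM in the same clusters. The ciliated-like cluster 22 held 67 and 28 cells with medians of 1890 and 2578 UMIs. Yet its leading genes Tmem212, Ccdc153 and Dynlrb2 were counted 16, 8 and 18 times in all DOX cells, against 940, 661 and 579 in DOX plus AMH. Its name is therefore doubtful for the DOX cells, and its counts do not show more ciliated cells in DOX. Of the genes measured, 486 were at least 1.5-fold apart in opposite directions in 2 classes, 39 of them named by the rule. Ly6g, of neutrophils, was 0.349 and 0.101 CPM, against the direction of S100a8.

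A hypothesis was that the higher Id1, Id2 and Id3 in smooth muscle-like cells are a response of cells that carry the receptor Amhr2. Log2 ratios were higher in cluster 8, which had more Amhr2, than in cluster 16 for 3 of the 3 Id genes, with intervals apart, but the test was drawn up from these values and supports nothing. Within cluster 8, cells with an Amhr2 UMI had a summed Id log2 ratio of 2.19 (2.0 to 2.38) and cells without one 1.82 (1.71 to 1.92). The difference of 0.37 met the prediction set beforehand for that cluster. The intervals cover UMIs summed over cells and not the spread between cells. In DOX, cells with an Amhr2 UMI already had more Id transcripts, at 379.5 against 224.1 CPM. So the difference cannot decide for or against the hypothesis. Most cells without a UMI may still carry the receptor at this depth, and 61 and 78 cells had one.

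Other cells went both ways. Mesothelial-like cells, the class with the next highest Amhr2 at 1.74 and 4.10 CPM, had 1.06, 1.67 and 1.22 for Id1, Id2 and Id3. Over the 17 other clusters compared, each with less Amhr2 CPM than cluster 16 in both libraries, the interval lay above 0 in 3 and below 0 in 1 for Id1, in 5 and 2 for Id3, and in 12 and 1 for Id2, so Id2 was higher in most of them and Id1 and Id3 in few. Of these, stromal-like cluster 9, with Amhr2 at 0.272 and 0.192 CPM (3 and 1 UMIs), goes against it, with 1.49 (1.03 to 1.95) for Id1, 0.54 (0.35 to 0.73) for Id2, 0.77 (0.66 to 0.88) for Id3 and 2.16 (0.95 to 3.49) for Smad9. Vascular endothelial-like cells, with Amhr2 at 0.922 and 1.01 CPM, had 0.20 for Id1, -0.57 for Id2, or 0.79 without clusters 7, 11 and 23, and 0.76 for Id3. The values of Id1 and Id3 include cluster 11, which was found in DOX alone. The immediate-early list, which dissociation also induces, was higher in cluster 8, at 0.52 (14 of 21 genes at least 1.3-fold higher), than in cluster 16, at 0.20 (9 of 21 genes at least 1.3-fold higher), with Fos at 1.19 and 0.10, and was 0.41 in cluster 9. A response to the hormone, a difference in dissociation and other pools of animals all stay open.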
